A study of Mus musculus with 8 samples.

How the data were processed

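Mature microRNAs (miRNAs) were measured on 8 single-colour arrays of mouse embryonic fibroblasts, primary connective-tissue cells from embryos. Per the labels, the cells came from ATM+/+ and ATM-/- littermates, where ATM is the kinase that signals DNA double-strand breaks. They were treated with neocarzinostatin (NCS), a radiomimetic drug that makes such breaks, and harvested at 0, 4, 8 and 24 h. Per the labels' protocols, total RNA was extracted with Trizol and 4 µg were labelled with a platinum-based miRNA labelling kit. There was 1 array per genotype and time, so no comparison between single times has replicates. The number of arrays limits the precision of all values.

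The value table deposited by the authors holds a ratio for 431 probes: each array is divided, probe by probe, by the 0 h array of its genotype, and all 431 rows hold 1 in both 0 h columns. It therefore gives responses to NCS and no difference between genotypes at 0 h. The authors also deposited 6 comparison sheets, each of 1 treated array against its 0 h array. Below, the authors' deposited table means these sheets, and the ratio table means the value table. Per the file headers, a sheet gives a normalized intensity per probe and array, a coefficient of variation, a log2 ratio of the 2 intensities and a p-value. The log2 ratio in the deposited sheets equals the log2 of treated over 0 h intensity. The test behind the deposited p-value and the rule by which probes were listed in a sheet are not given in the sources used here, nor are the scanner processing and background correction. The 0 h intensities of a genotype differ between its sheets by 1 constant factor, from 0.821 to 1.24 against the 4 h sheet, so each sheet was scaled for its own pair.

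The sheets for ATM+/+ cells list 311, 298 and 313 probes at 4, 8 and 24 h, and those for ATM-/- cells list 185, 154 and 126. Probe names came from the sheets: 272 of the 431 probes of the ratio table were named this way, and the other 159 are unnamed here. Another 74 sheet probes lie outside the ratio table. Sheet columns were tied to genotypes through the slide lists deposited with them. Across probes, which are not independent replicates, the ratio table and the sheets correlated with Pearson's r from 0.935 to 0.949 in ATM+/+ cells. The same correlation was 0.760, 0.817 and 0.913 in ATM-/- cells at 4, 8 and 24 h. In the ATM-/- sheet at 8 h the ratio table lay above the sheet by a median of 0.61 on the log2 scale, and 59.2% of probes had the same sign in both. Median coefficients of variation between spots were 9.20% to 13.4%.

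Responses were computed as log2 of the deposited ratio, with no pseudocount, because the table holds ratios and not the expression levels assumed beforehand. A change of at least 2-fold was counted, and the mean over 4, 8 and 24 h was given with the SD over times. The 3 times share a single 0 h array and are not replicates. Time points were also taken as repeats in a linear model (limma 3.58.1 in R 4.3.3, with lmFit and eBayes), with contrasts for treated against 0 h in each genotype and for their difference, on 4 residual degrees of freedom. Calls had a Benjamini-Hochberg adjusted p under 0.05. Genotype levels were compared with limma on log2 intensities from the sheets, with time as a block and 3 residual degrees of freedom, over 118 miRNAs from the 120 probes present in all 6 sheets. Sheets of the 2 genotypes were normalized separately, so this comparison was read with that limit and under 4 scalings. For all of them, the 8 and 24 h sheets were first multiplied by a constant factor each. It matched their 0 h values to the 4 h sheet of the same genotype. The first scaling used these intensities, is called the deposited scale here, and depends on that choice of reference sheet. In the others, arrays were centred on each array's median, quantile normalized, or scaled to each array's 75th percentile. Probes of one name were averaged.

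Both models were tested on simulated data. For the genotype comparison over 118 miRNAs, 70.0% of simulated log2 differences of 1 and 95.7% of those of 2 were recovered. For treated against 0 h over 431 features, the shares were 19.25% and 75.0%. The false share of calls was 2.36% and 3.58%. The simulations had independent normal noise per miRNA and array, equal effects at all affected times, and no shift, chip or position effect between arrays. The simulated 0 h array had the spread of the treated ones. These shares therefore do not measure the error rate of calls in the real arrays.

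Lists of miRNAs were fixed before the data were examined, from general knowledge: the let-7, miR-15/16, miR-29, miR-30, miR-181, miR-199/214 and miR-23/24/27 families, miR-17-92 with its paralogs, p53-linked miRNAs, miRNAs whose maturation is linked to the RNA-binding protein KSRP, miRNAs reported to target ATM, H2AX or BRCA1, the Dlk1-Dio3 and Sfmbt2 clusters, and markers of pluripotent, epithelial, blood, muscle, neural, liver and endothelial cells. That knowledge may include the study behind this series, so the KSRP-linked list is not independent evidence of its direction. The median of a list was placed among 10000 random lists of the same size, matched on mean intensity in 5 bins. For the difference of the responses, the ATM+/+ intensity was used for matching. For genotype levels, camera with a preset correlation of 0.01 and with an estimated one, and fry, were run on lists with at least 3 members. The rule for named miRNAs, also fixed beforehand, took for each genotype the 10 highest and 10 lowest mean changes among those changed the same way at all 3 times. It took the 10 largest differences of the responses each way, up to 10 genotype calls each way, the 4 members of each list with the highest mean level, and miR-34a, miR-34b, miR-34c, miR-21, miR-16 and let-7a. Where fewer than 10 were called, the remaining places went to miRNAs that differed the same way at all 4 times.

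Alternatives were other scalings, a pseudocount, a filter on level, the brightest probe per name, leaving out each time, the sheets in place of the ratio table, no time block, an intensity trend with a robust prior, and a linear trend over time. Chosen after seeing the data were chip as a block, restriction to miRNAs listed in the sheets, and the other scalings applied to the sheets. Each chip held 2 arrays: 0 and 4 h of a genotype shared one chip, and 8 and 24 h another. The 0 and 8 h arrays lay at position 1 of their chips, and the 4 and 24 h arrays at position 2. Genotype and chip cannot be told apart. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The Atm transcript is not measured on a miRNA array, so the genotype labels could not be checked against it.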

Results

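Mature miRNA levels were profiled in ATM+/+ and ATM-/- mouse embryonic fibroblasts at 0, 4, 8 and 24 h after NCS, with 1 array per genotype and time. The question addressed was which miRNAs differ in level after DNA damage and whether this depends on ATM. No group has replicates, and errors given as SD are over the 3 treated times or, for genotype levels, over the 4 times. Responses are log2 ratios to the 0 h array of the same genotype over 431 probes, of which 272 carry a miRNA name here. The medians of all probes were 0.03, 0.23 and -0.12 at 4, 8 and 24 h in ATM+/+ cells and -0.23, 0.03 and 0 in ATM-/- cells, so single values are read against these shifts. Median intensities of the 0 h arrays in the 4 h sheets were 69.2 in ATM+/+ and 56.7 in ATM-/- cells, over 311 and 185 listed probes.

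In ATM+/+ cells miR-146a, a regulator of inflammatory signalling, had a mean log2 ratio to 0 h of 2.11 ± 0.42 (SD over 3 times). The p53-induced miR-34c and miR-34b-5p stood at 1.85 ± 0.27 and 1.65 ± 0.18, and their relative miR-34a stood at 0.80 ± 0.29. miR-100 was at 1.53 ± 0.14, miR-495 at 1.41 ± 0.13, miR-410 at 1.40 ± 0.36, and miR-199a-3p/miR-199b at 1.36 ± 0.33. The let-7 members let-7f, let-7a and let-7d, which repress growth-promoting genes, had means of 1.40 ± 0.34, 1.30 ± 0.37 and 1.25 ± 0.26. miR-21, abundant in these cells, was at 1.23 ± 0.28, and miR-16, which targets cell cycle regulators, at 0.82 ± 0.07. The 0 h intensities of miR-146a, miR-34c, miR-34b-5p, miR-100, miR-495 and miR-410, which are 6 of the 10 highest, lay from 18.0 to 26.5, under the 10th percentile of the sheet intensities (27.2), so the sizes and order of these 6 are uncertain. The 0 h intensities of let-7f, miR-199a-3p/miR-199b, let-7a and let-7d were 257, 317, 512 and 273.

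The lowest ATM+/+ values belonged to miR-694 with -1.87 ± 0.29, miR-882 with -1.68 ± 0.83, miR-190b with -1.64 ± 0.92 and miR-1187 with -1.49 ± 0.61. They were followed by miR-669c at -1.46 ± 0.64, miR-1897-5p at -1.43 ± 0.57, miR-1186 at -1.43 ± 0.51 and miR-692 at -1.37 ± 0.35. The last of the 10 were miR-291a-5p at -1.35 ± 0.26 and miR-1903 at -1.34 ± 0.54. At least 1 treated ATM+/+ array lay under the intensity of 27.2 for 5 of these 10, namely miR-694, miR-190b, miR-1186, miR-692 and miR-291a-5p, so their sizes and order are uncertain. Among the 272 named miRNAs, 28 were at least 2-fold higher and 40 at least 2-fold lower at 4 h, 21 and 18 at 8 h, and 44 and 27 at 24 h. Over all 431 probes these counts were 31 and 42, 26 and 18, and 45 and 56. With arrays centred on their medians the 8 h balance turned, to 13 higher and 36 lower. On the mean of the 3 times, 26 of the 431 probes were at least 2-fold higher and 31 at least 2-fold lower. The log2 ratios in the authors' deposited table gave 14 higher and 50 lower over another set, the 284 probes in all 3 ATM+/+ sheets. That set holds probes outside the ratio table and no unnamed probes.

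Lists fixed beforehand showed where these values gathered. All 9 measured let-7 members were above 0 h at all 3 times in ATM+/+ cells, 6 of them with a mean of at least 2-fold, and their medians were 1.07, 0.99 and 1.54 at 4, 8 and 24 h. The median of their means was 1.13, at percentile 99.9 of random lists of matched level. Members of this family are nearly identical in sequence and may share signal on an array, so they are not separate measurements. Of 19 KSRP-linked miRNAs, 17 were above 0 h at all 3 times and 8 averaged at least 2-fold, with a median of 0.87 at percentile 99.9. Of these 19, 5 are also let-7 members. miR-125b-5p stood at 1.19 ± 0.13, let-7i at 0.97 ± 0.17, let-7g, a let-7 member outside this list, at 0.99 ± 0.22 and miR-145 at 0.52 ± 0.33. The 1 member below 0 h at all 3 times was the muscle miRNA miR-206, at -0.61 ± 0.03. Within a chip, the KSRP-linked median was 0.90 for 4 h against 0 h and 0.48 for 24 h against 8 h. Both set position 2 of a chip against position 1. At equal positions on separate chips, the median was 0.75 for 8 h against 0 h and 0.22 for 24 h against 4 h.

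The 7 p53-linked miRNAs had a median of 0.80 in ATM+/+ cells (percentile 90.8), with 6 above 0 h at all 3 times; miR-107 was at 0.79 ± 0.13 and miR-143 at 0.87 ± 0.25. All 5 members of miR-23/24/27 were above 0 h at all times, with a median of 0.88 (percentile 86.5) and values of 1.12 ± 0.42 for miR-23a, 0.88 ± 0.33 for miR-24, 0.81 ± 0.15 for miR-27b and 0.77 ± 0.24 for miR-27a. Of the 12 measured members of miR-17-92 and its paralogs, a cluster linked to proliferation, 11 were above 0 h at all times, with a median of 0.63 (percentile 96.5) and none at 2-fold; miR-20a was at 0.66 ± 0.32, miR-19b at 0.63 ± 0.03, miR-17 at 0.41 ± 0.15 and miR-106a at 0.37 ± 0.11. The 6 miRNAs reported to target ATM, H2AX or BRCA1 had a median of 0.89 (percentile 99.1), from miR-146a down to miR-138 at 0.06 ± 0.07, with miR-18a at 0.90 ± 0.17. The 3 members of miR-15/16 had a median of 0.75 (percentile 95.1), with miR-15b at 0.75 ± 0.22 and miR-15a at 0.64 ± 0.14, and the 3 of miR-29 a median of 0.81 (84.7), with miR-29b at 1.13 ± 0.09 and miR-29a at 0.81 ± 0.25. The 5 members of miR-30 had a median of 0.49 (80.4), with miR-30a at 0.89 ± 0.19, miR-30d at 0.49 ± 0.09 and miR-30e at 0.28 ± 0.03. The 4 members of miR-181 had a median of 0.55 (85.5), with miR-181a at 0.67 ± 0.21, miR-181b at 0.58 ± 0.27, miR-181d at 0.52 ± 0.12 and miR-181c at 0.48 ± 0.25. miR-214 was at 0.85 ± 0.18. The 39 imprinted Dlk1-Dio3 miRNAs had a median of 0.24 (percentile 84.4), with miR-127 at 0.51 ± 0.16, miR-541 at 0.57 ± 0.25, miR-665 at -0.03 ± 0.17 and miR-494 at -1.10 ± 0.72.

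The Sfmbt2 cluster, a large rodent repeat-like family of near-identical miRNAs, lay on the other side. Of its 27 measured members, 20 were below 0 h at all 3 times in ATM+/+ cells and 8 averaged at least 2-fold lower. Its medians were -0.92, -0.56 and -0.58 at 4, 8 and 24 h, and the median of means was -0.76, at percentile 0 of random lists. Near-identical members may share signal on an array, so they are not separate measurements, which random lists do not allow for. Between treated arrays the median change was 0 from 8 to 24 h and 0.585 from 4 to 24 h. The lower values therefore rest on the single 0 h array, and 1 deviating 0 h array could give them. miR-466f-3p was at -1.24 ± 0.52, miR-466c-5p at -1.16 ± 0.62 and miR-467f at -0.88 ± 0.52. Muscle miRNAs were also below 0 h at all times, 4 of 4, with a median of -0.67 (percentile 5.12); miR-133a was at -0.94 ± 0.65, miR-133b at -0.70 ± 0.23 and miR-1 at -0.63 ± 0.24. For markers of pluripotent cells the median over 4 members was -0.55 (percentile 8.75), with miR-302c at -1.01 ± 0.22, miR-291b-5p at -0.09 ± 0.34 and miR-302b at 0.71 ± 0.04. Epithelial and blood markers, with 3 members each, had medians of -0.06 and -0.23, the first of either sign over the alternative settings. Among them were miR-141 at -0.39 ± 0.17, miR-200b at 0.10 ± 0.12, miR-200a at -0.06 ± 0.23, miR-223 at -0.46 ± 0.47, miR-150 at -0.23 ± 0.31 and miR-486 at 0.93 ± 0.17. The neural miR-129-5p was at 0.17 ± 0.17 and the endothelial miR-126-5p at -0.12 ± 0.46. The liver marker list had 0 measured members.

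**Figure D1:**
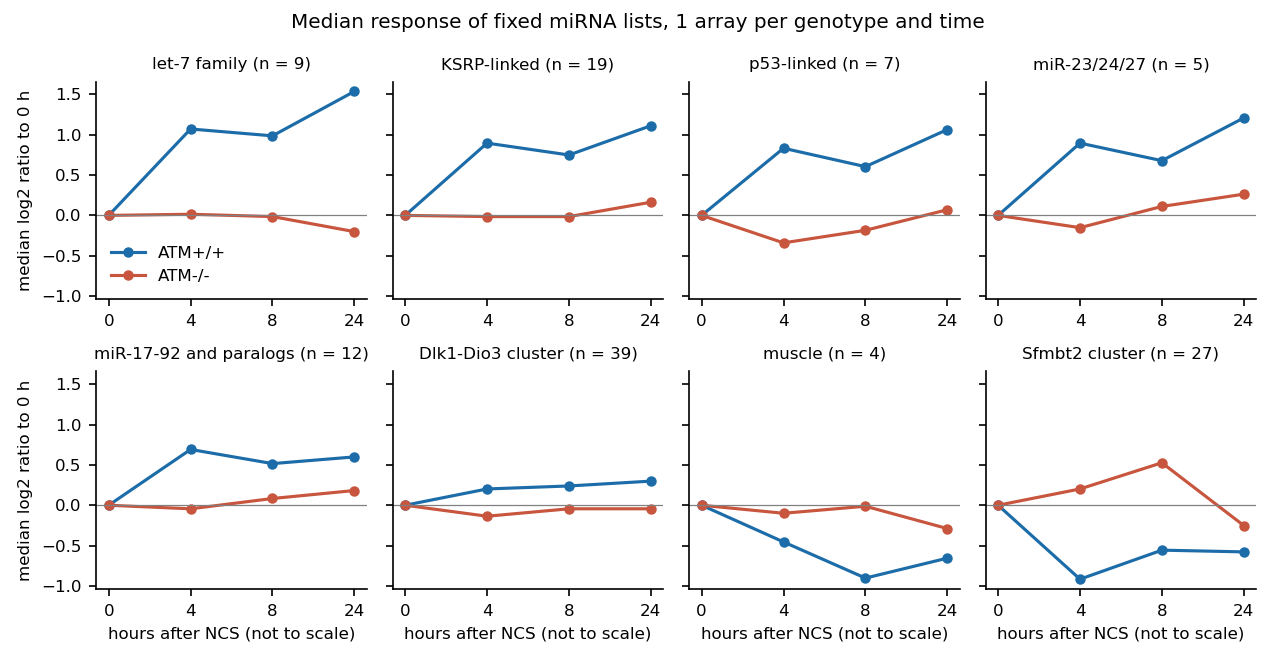
Median log2 ratio to 0 h (vertical axis) of 8 fixed miRNA lists at 0, 4, 8 and 24 h after NCS (horizontal axis, evenly spaced), in ATM+/+ (blue) and ATM-/- cells (red), with 1 array per point. The let-7 median in ATM+/+ cells reaches 1.54 at 24 h against -0.20 in ATM-/- cells, and the Sfmbt2 median lies at -0.92 at 4 h in ATM+/+ cells against 0.20.

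In ATM-/- cells fewer values left the 2-fold range. On the mean of the 3 times, 4 probes of the ratio table were at least 2-fold higher, namely miR-485 at 1.68 ± 0.54, miR-1902 at 1.52 ± 0.59, miR-1188 at 1.16 ± 0.69 and miR-685 at 1.05 ± 1.01, and 1 unnamed probe was at least 2-fold lower. miR-1899 followed at 0.98 ± 0.60, the smooth muscle and fibroblast miRNA miR-143 at 0.84 ± 0.20, miR-298 at 0.72 ± 0.46, miR-1907 at 0.71 ± 0.76, miR-93 at 0.71 ± 0.11 and miR-1195 at 0.67 ± 0.54. These 10 and the 10 lowest named next are limited to miRNAs that had the same sign at all 3 times. Low values were those of miR-30c at -0.88 ± 0.20, miR-34b-5p at -0.80 ± 0.27, miR-466l at -0.73 ± 0.09, miR-342-3p at -0.68 ± 0.46 and miR-542-3p at -0.66 ± 0.20. They were followed by miR-34c at -0.65 ± 0.54, the hypoxia-linked miR-210 at -0.62 ± 0.27, miR-379 at -0.60 ± 0.56, miR-17 at -0.59 ± 0.45 and miR-29c at -0.59 ± 0.16. Of these 10 lowest, 9 are in no ATM-/- sheet. Over all probes, 5 were at least 2-fold higher and 19 at least 2-fold lower at 4 h, 22 and 13 at 8 h, and 3 and 11 at 24 h. Among the 272 named miRNAs these counts were 5 and 4, 22 and 5, and 3 and 10. With each array centred on its median, the 4 h counts became 14 and 7. The count higher on the mean was 2 without the 8 h array and 7 without the 24 h array, and 6 were lower without the 24 h array. The log2 ratios in the authors' deposited table gave 1 higher on the mean, and 0 with quantile normalization. At 8 h the ratio table lay above that table by a median of 0.61, and miR-485 stood at 2.07 in the ratio table and 0.87 in the authors' deposited table. miR-143 and miR-93 changed sign there, from 0.81 and 0.82 to -0.10 and -0.12 in the authors' deposited table, so their sign at all 3 times holds in the ratio table alone.

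The list medians in ATM-/- cells were -0.09 for let-7 (percentile 25.8), -0.02 for KSRP-linked miRNAs (80.3), -0.13 for p53-linked miRNAs (18.8), 0.04 for miR-23/24/27 (59.7) and 0.00 for miR-17-92 and paralogs (70.7). Of the 9 let-7 members 1 was above 0 h at all 3 times, as were 4 of the 19 KSRP-linked miRNAs. The let-7 median moved between -0.49 and 0.07 over the alternative settings, so it has no settled direction. miRNAs reported to target ATM, H2AX or BRCA1 had a median of 0.34 (percentile 97.3), with miR-24 at 0.55 ± 0.17, miR-18a at 0.29 ± 0.14 and miR-138 at 0.58 ± 0.61. Other medians were -0.32 for miR-15/16, -0.06 for miR-29, -0.30 for miR-30, 0.03 for miR-181, -0.10 for Dlk1-Dio3 miRNAs and 0.10 for the Sfmbt2 cluster. Over the alternative settings the medians of KSRP-linked, miR-23/24/27, miR-17-92, miR-29, miR-181, Dlk1-Dio3, Sfmbt2 and blood lists also took either sign. miR-214 was at 0.31 ± 0.16 and miR-199a-3p/miR-199b at -0.07 ± 0.23. For markers of other cells they were 0.24 in pluripotent, -0.43 in epithelial, 0.01 in blood and -0.16 in muscle lists. miR-129-5p was at 0.29 ± 0.28 and miR-126-5p at -0.41 ± 0.45.

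The difference of the responses, ATM+/+ minus ATM-/-, addresses whether the response depends on ATM. Among miRNAs with a difference of one sign at all 3 times, it was highest for miR-34c at 2.50 ± 0.28, miR-34b-5p at 2.45 ± 0.37, miR-30c at 2.03 ± 0.59, miR-100 at 1.92 ± 0.42 and let-7c at 1.77 ± 1.28. miR-146a at 1.73 ± 0.63, miR-410 at 1.67 ± 0.41, miR-495 at 1.54 ± 0.35, let-7a at 1.49 ± 0.84 and miR-362-5p at 1.48 ± 0.47 completed the 10 highest. It was lowest for miR-185 at -1.87 ± 0.85, miR-1902 at -1.86 ± 0.94, miR-1187 at -1.70 ± 1.25, miR-466f-3p at -1.66 ± 1.02 and miR-694 at -1.63 ± 0.52. These were followed by miR-291a-5p at -1.60 ± 0.36, miR-1186 at -1.52 ± 0.26, miR-696 at -1.49 ± 0.88, miR-190b at -1.48 ± 1.14 and miR-466j at -1.44 ± 0.82. Over all probes the mean difference was at least 1 for 43 and at most -1 for 38, and per time these counts were 65 and 48 at 4 h, 72 and 51 at 8 h, and 44 and 55 at 24 h. With arrays centred, 45 lay above at 8 h. Over the 272 named miRNAs the counts were 45 and 46 at 4 h, 46 and 50 at 8 h, and 44 and 23 at 24 h. Restricted to miRNAs listed in the sheets of both genotypes, they were 10 and 36 at 4 h, 7 and 40 at 8 h, 17 and 3 at 24 h, and 9 and 20 on the mean. The balance over all probes thus turned at each time. Leaving out unnamed probes alone made it near even at 4 and 8 h and turned it at 24 h. In the lists, the median difference was 1.30 for let-7 (percentile 99.97), with 8 of 9 members higher in ATM+/+ cells at all times, 0.89 for KSRP-linked miRNAs (14 of 19) and -0.81 for the Sfmbt2 cluster (12 of 27 lower at all times). miR-21 differed by 1.25 ± 0.67, miR-34a by 0.92 ± 0.15 and miR-16 by 1.14 ± 0.23.

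Low signal limits these differences. Of the 10 highest, 8 had an ATM+/+ 0 h intensity under 27.2, and of the 10 lowest, 5 had a treated ATM+/+ array under it. Of the 10 miRNAs with the highest differences, 7 are in no ATM-/- sheet, and of the 19 KSRP-linked miRNAs 6 are in all 3 ATM-/- sheets against 18 in all 3 ATM+/+ sheets. Of the 9 let-7 members, 3 are in all 3 ATM-/- sheets against 9 in all 3 ATM+/+ sheets. The percentile of the let-7 difference was matched on ATM+/+ intensity alone, so low ATM-/- signal is not matched out. Only 3 KSRP-linked miRNAs exceeded 52.2, the median ATM-/- 0 h intensity over the 191 miRNAs listed in at least 1 ATM-/- sheet. Their mean responses in ATM+/+ and ATM-/- cells were 1.19 and -0.00 for miR-125b-5p, 0.87 and 0.84 for miR-143, and 0.52 and 0.18 for miR-145. In the authors' deposited table they were 0.96 ± 0.16 and -0.23 ± 0.45, 0.63 ± 0.26 and 0.38 ± 0.44, and 0.28 ± 0.31 and -0.05 ± 0.28. Over the 79 named miRNAs above that intensity the median difference was -0.01, with 29 higher and 19 lower in ATM+/+ cells at all 3 times. Across the 431 probes, which are not independent replicates, the mean responses of the genotypes correlated with Pearson's r of -0.02.

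**Figure D2:**
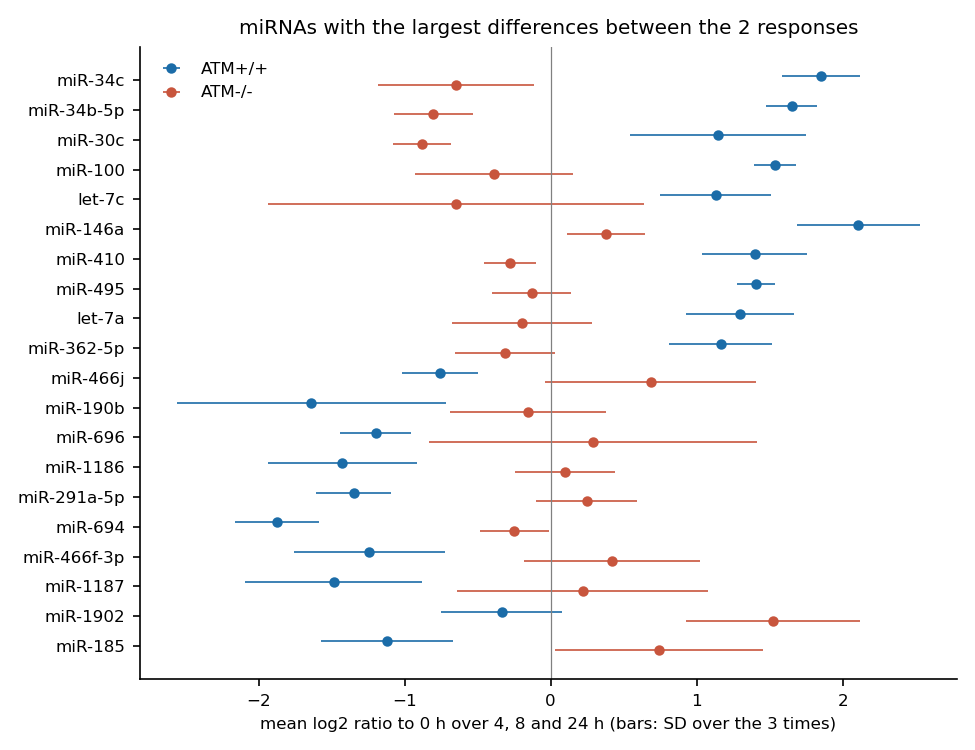
Mean log2 ratio to 0 h over 4, 8 and 24 h (horizontal axis) of the 10 miRNAs with the highest and the 10 with the lowest difference of the responses, in ATM+/+ (blue) and ATM-/- cells (red); bars are the SD over the 3 times. miR-34c stands at 1.85 in ATM+/+ and -0.65 in ATM-/- cells, and miR-1902 at -0.34 and 1.52.

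With the treated times taken as repeats, limma called 0 of 431 features in ATM+/+ cells, 0 in ATM-/- cells and 0 for the difference of the responses. At an unadjusted p under 0.05 there were 60, 4 and 27, and the lowest adjusted p values were 0.109, 0.996 and 0.321. These counts depend on single arrays: they were 27, 3 and 12 without 4 h, 68, 2 and 21 without 8 h, and 64, 21 and 62 without 24 h. With an intensity trend and robust prior, limma called miR-146a (adjusted p = 0.0185), miR-34b-5p (0.0207) and miR-34c (0.0207) in ATM+/+ cells, and miR-34b-5p for the difference (0.0262). Each of these was higher at 3 of 3 times in ATM+/+ cells. The 0 h arm is 1 array and the error comes from the spread of the treated times, and the 0 h intensities of the 3 (24.4, 18.0 and 22.2) lay under 27.2, so 1 deviating 0 h value would give the same calls. Adjusted over the list alone, the ATM+/+ calls were 5 let-7, 3 KSRP-linked, 2 p53-linked, 2 ATM, H2AX or BRCA1 targeting, 2 pluripotent and 1 miR-29 members and both of miR-199a-3p/miR-199b and miR-214, against 0 calls in each list over all features. For the difference they were 2 p53-linked, 2 ATM, H2AX or BRCA1 targeting and 1 miR-30 members. With chip as a block, which rests on 4 h against 0 h, there were 0 calls and 33, 5 and 17 features at an unadjusted p under 0.05. In ATM+/+ cells 59.4% of features had the same sign at all 3 times, against 49.8% in simulated unchanged arrays that share a 0 h array, and in ATM-/- cells 33.9% against 50.05%. The mean covariance between times was 0.367 against 0.186 simulated in ATM+/+ cells and 0.0626 against 0.188 in ATM-/- cells. The simulation gave the 0 h array the spread of the treated arrays and no shift between arrays. ATM-/- values lay under it, so it does not describe these arrays, and the ATM+/+ excess over it is not read as agreement. Part of any agreement between times may come from the shared 0 h array, which cannot be split.

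Probes at least 2-fold away from 0 h with an unadjusted p under 0.05 in the authors' deposited table for ATM+/+ cells were 20 higher and 51 lower at 4 h, 10 and 25 at 8 h, and 18 and 49 at 24 h. In the authors' deposited table for ATM-/- cells they were 2 and 0, 4 and 4, and 3 and 15, with fewer probes listed.

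Levels in the 2 genotypes, irrespective of treatment, were compared over the 118 miRNAs present in all sheets. All 3 ATM+/+ sheets held 284 probes, all 3 ATM-/- sheets 123, and all 6 sheets 120. This filter therefore leaves out mostly miRNAs listed in ATM+/+ cells and not in ATM-/- cells. Scalings, counts and list shares below cover only the miRNAs that remain. miR-21 was higher in ATM+/+ cells by 5.99 ± 0.30 (SE, limma adjusted p = 1.23e-09), with 0 h intensities of 1059 and 32.3. Also higher were miR-199a-3p/miR-199b at 4.76 ± 0.32, miR-23b at 4.23 ± 0.29, let-7a at 4.15 ± 0.31, miR-23a at 3.14 ± 0.26 and miR-125b-5p at 3.03 ± 0.29. miR-130a at 2.82 ± 0.27, miR-143 at 2.78 ± 0.25, let-7e at 2.71 ± 0.26 and miR-494 at 2.62 ± 0.38 completed the 10, and the highest limma adjusted p among them was 4.04e-05. For miR-21, miR-199a-3p/miR-199b and miR-23b at least 1 ATM-/- array lay under the 10th percentile of intensities (27.2), and signal above background was not shown there, so these sizes and their order are uncertain. With that intensity as a pseudocount the differences were 5.04 ± 0.24, 3.61 ± 0.25 and 3.43 ± 0.23, each called by limma. Lower in ATM+/+ cells were miR-1899 by -1.27 ± 0.29 (adjusted p = 0.00218) and miR-714 by -0.84 ± 0.26 (0.0121), while let-7b* at -0.62 ± 0.26 (0.0643) and miR-483* at -0.39 ± 0.26 (0.231) did not pass on the deposited scale and were called lower under each of the other 3 scalings described next. On the deposited scale miR-145 and miR-24 differed by 0.30 ± 0.25 (adjusted p = 0.332) and 0.60 ± 0.25 (0.0643). miR-145 was called lower in ATM+/+ cells under the other 3 scalings, at -0.74 (adjusted p = 0.0288), -0.85 (0.00768) and -0.96 (0.00374) with centred, quantile normalized and 75th-percentile scaled arrays, so its direction turned. miR-24 turned to -0.44 and -0.61, neither called, and to -0.67 (0.0442).

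On the deposited scale limma called 56 miRNAs higher and 2 lower in ATM+/+ cells around a median difference of 0.70, and the split depended on scaling. It was 25 and 42 with arrays centred on their medians (median difference -0.34), 25 and 32 with quantile normalization (-0.29) and 23 and 57 with scaling to the 75th percentile (-0.56). With centred and 75th-percentile scaled arrays, the lowest limma adjusted p values were 9.29e-43 and 1.09e-39. There the adjusted p followed the size of the difference alone, as with a single variance for all miRNAs. Calls under these 2 scalings therefore do not reflect the spread of each miRNA. Called higher under all 4 scalings were 23 miRNAs, and called lower under all 4 were miR-1899 and miR-714. On the deposited scale each of the 23 was higher at 4 of 4 times. Signs at single times were not taken under the other 3 scalings. On the deposited scale the differences of miR-1187 and miR-574-5p at 4 h were 0.50 and 0.60, under the median difference of 0.70. The 23 include the 10 named above, 3 of 4 let-7, 5 of 8 KSRP-linked, 2 of 3 miR-23/24/27, 3 of 12 Sfmbt2, 2 of 6 miR-17-92 and 2 of 15 Dlk1-Dio3 miRNAs. Not called lower on the deposited scale but called lower under the other 3 were 2 of the 8 KSRP-linked, 1 of the 4 let-7, 3 of the 15 Dlk1-Dio3 and 1 of the 3 miR-30 miRNAs. On the deposited scale the calls higher were 5 KSRP-linked (5 adjusted over the list alone), 3 let-7 (3), 6 miR-17-92 (6), 7 Dlk1-Dio3 (7), 8 Sfmbt2 (8) and 2 miR-23/24/27 (3) miRNAs. Adjusted over the let-7 list alone, let-7b* was also called, as lower. With arrays centred, the median difference went from 0.60 to -0.44 for Dlk1-Dio3 and from 1.02 to -0.03 for Sfmbt2 miRNAs, and from 2.91 to 1.87 for KSRP-linked miRNAs. No list passed camera, with an adjusted p of 0.110 for the KSRP-linked list and adjusted p = 0.552 with an estimated correlation. fry, which does not compare a list with other miRNAs, gave an adjusted p of 9.94e-04 each for the KSRP-linked, Dlk1-Dio3 and miR-17-92 lists, 0.00226 for miR-23/24/27, 0.00821 for let-7, 0.114 for Sfmbt2 and 0.232 for miR-30. The sheets of the genotypes were normalized separately, each genotype was on its own chips, and the labels name no separate cultures, so p-values measure only the spread between these arrays. RNA recovery, RNA quality and labelling were not tested here. A difference in them between the samples of the 2 genotypes cannot be told apart from genotype, also for miR-21.

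**Figure D3:**
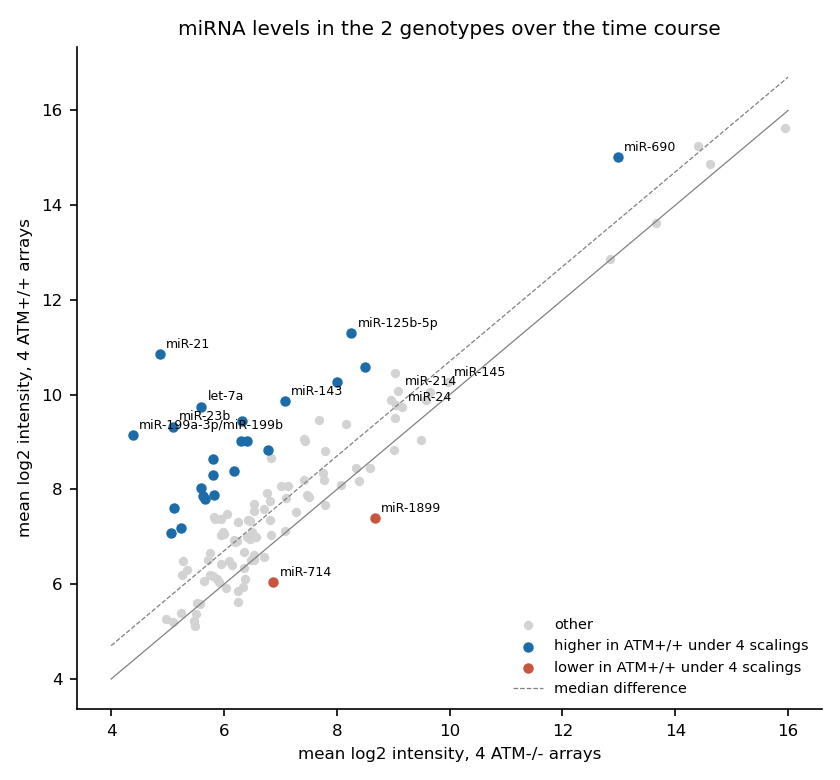
Mean log2 intensity of 118 miRNAs over the 4 arrays of ATM-/- cells (horizontal axis) and of ATM+/+ cells (vertical axis); the solid line marks equal values and the dashed line the median difference of 0.70. Blue points are the 23 miRNAs called higher in ATM+/+ cells under 4 scalings and red points the 2 called lower; miR-21 lies above the lines, and miR-145 and miR-24 lie near them.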

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

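The tests reported here were chosen after the results were seen. Over the named probes, 23 miRNAs lay above 0 h in ATM+/+ cells and below it in ATM-/- cells at all 3 times, and 14 the other way round. Among the 20 miRNAs named for the difference of the responses, 4 were of the first kind. The differences of their mean log2 responses were 2.50 for miR-34c, 2.45 for miR-34b-5p, 2.03 for miR-30c and 1.67 for miR-410. Of the other kind, 1 of the 20 was miR-1902, with a difference of -1.86. With 1 array per genotype and time, the difference was not tested at single times. In limma's test of the difference over times none of the 5 passed, and miR-34b-5p alone passed with an intensity trend and robust prior. The 4 with higher ATM+/+ values are in no ATM-/- sheet. In simulated unchanged arrays that share a 0 h array, 49.8% and 50.05% of features had the same sign at all 3 times in ATM+/+ and ATM-/- cells. Opposite signs at all 3 times therefore also arise without any change. No expected count was computed, so the counts of 23 and 14 are not read as an excess.

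Outside the ratio table, 2 miRNAs were at least 2-fold away from 0 h in all 3 ATM+/+ sheets at an unadjusted p under 0.05. Their mean log2 ratios in the authors' deposited table were 1.61 for miR-22* and -1.67 for miR-574-5p. In ATM-/- cells miR-574-5p stood at 0.48 (p = 0.00224), -0.08 (p = 0.304) and -0.98 (p = 1.77e-04) at 4, 8 and 24 h in the authors' deposited table, against -2.28, -1.34 and -1.39 in ATM+/+ cells. miR-22* is in no ATM-/- sheet. The ATM+/+ 0 h intensity of miR-22* was 14.8, under the 10th percentile of the sheet intensities (27.2), so the size of its ratio is uncertain.

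Of the 19 KSRP-linked miRNAs, 17 were above 0 h at all 3 times after NCS in ATM+/+ cells, and 1 was below it. With arrays centred on their medians the lower quartile of the members' mean changes was 0.59. The medians removed were 0.03, 0.23 and -0.12 at 4, 8 and 24 h, so centring could move this quartile only a little. It argues only against 1 factor per array, estimated by the median, as the whole cause. Centring does not remove scaling that depends on intensity. At 4 h, on the chip of the 0 h array, the lower quartile was 0.76, so a difference between chips does not account for the 4 h values. With 17 of 19 members above 0 h at all times this quartile had to lie above 0, so it is not a separate test. For 8 and 24 h, on another chip, an effect of the chip stays open. The 4 h and 0 h arrays lay at different positions of their shared chip, and position was not tested. A single 0 h array with low values for these miRNAs may produce the pattern. The list's median changes from 4 to 24 h and from 4 to 8 h lay at percentiles 47.3 and 17.3 of random lists. The change from 8 to 24 h, added later and free of the 0 h array, was 0.48 at percentile 99.8. That change sets position 2 of a chip against position 1, so array position may also underlie it. A deviating 0 h array, a response to NCS and an effect of time in culture cannot be told apart. There was 1 array at 0 h and no untreated array at later times.

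In ATM-/- cells the median of the same list was -0.02, with 4 of its 19 members above 0 h at all 3 times, and limma called 0 members for the difference of the responses. With centred arrays the lower quartile of the difference of the responses over the list was 0.41. This argues only against 1 factor per array, estimated by the median, and does not address scaling that depends on intensity. Low signal in ATM-/- cells cannot be told apart from a dependence on ATM, which stays open, for this list: only 3 members exceeded the median ATM-/- intensity at 0 h, under the minimum of 5 that was set once this number was known, and the lower quartile of their differences was 0.19. An earlier form of the test, on bright miRNAs picked for a higher ATM+/+ response, had spoken against low signal and was dropped because of that selection. Of the 3, miR-143 stood at 0.87 and 0.84 in the 2 genotypes in the ratio table but at 0.63 and 0.38 in the authors' deposited table, and miR-125b-5p at 1.19 and -0.00, and at 0.96 and -0.23.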

How the results depend on the processing

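Chip as a block, restriction to miRNAs listed in the sheets, and the sheets with quantile, 75th-percentile or pseudocount settings were chosen after seeing the data. Quantile, 75th-percentile, pseudocount and level-filter settings were not run on the ratio table, which holds no intensities. The genotype fit is matched on time, and without the time block it made 59 calls higher and 2 lower. For single times, no paired analysis was possible because each group has 1 array and the labels give no replicate numbers. Where values moved, the cause was not tested, except that the sheets list fewer probes. Of the values that answer the comparisons, 225 stayed within their spread or side of the threshold, 92 moved, 5 passed the threshold and 6 no longer did. Of those for named miRNAs and other lists, 1611 stayed within their spread or side of the threshold, 206 moved, 7 passed the threshold and 2 no longer did; none of these reversed a called value. The medians of KSRP-linked miRNAs in ATM+/+ cells ranged from 0.61 to 0.999 and of let-7 from 0.88 to 1.30. Signal over background is limiting in ATM-/- cells, where few probes are listed, and for dim miRNAs at 0 h in ATM+/+ cells.

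Counts are given as higher then lower, or as ATM+/+ above then below ATM-/-. With arrays centred, ATM+/+ counts were 13 and 36 at 8 h and 36 lower at 24 h, ATM-/- counts 14 and 7 at 4 h and 0 lower on the mean, and 45 were above at 8 h. With only miRNAs listed in the sheets, ATM+/+ cells had 24 lower at 24 h, and ATM-/- cells 0 lower at 4 h, 1 at 8 h and 0 on the mean. The differences were then 10 above at 4 h, 7 above at 8 h, 17 and 3 at 24 h, and 9 and 20 on the mean. From the sheets, ATM+/+ cells had 11 higher at 8 h, 17 higher at 24 h, and 14 and 50 on the mean. ATM-/- cells had 2 and 1 at 4 h, 4 higher at 8 h and 1 higher on the mean. Differences were 10 above at 4 h, 15 above at 8 h, 9 and 8 at 24 h, and 8 and 22 on the mean, and the ATM-/- let-7 median was -0.46.

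From quantile normalized sheets, ATM+/+ cells had 13 higher at 8 h and 28 at 24 h. ATM-/- cells had 0 and 1 at 4 h, 8 and 3 at 8 h, 7 higher at 24 h, and 0 and 0 on the mean. Differences were 16 above at 4 h, 17 and 30 at 8 h, 7 and 9 at 24 h, and 7 and 17 on the mean, and the ATM+/+ let-7 median was 0.90. From sheets scaled to the 75th percentile, ATM+/+ cells had 20, 9 and 17 higher at 4, 8 and 24 h and 10 and 50 on the mean. ATM-/- cells had 0 and 2 at 4 h, 3 higher at 8 h and 1 higher on the mean. Differences were 10 above at 4 h, 15 and 33 at 8 h, 9 and 8 at 24 h, and 8 and 22 on the mean, with let-7 medians of 0.94 and -0.49. From sheets with a pseudocount of 27.2, ATM+/+ cells had 5 and 2 higher at 4 and 8 h, 9 and 26 at 24 h, and 5 and 19 on the mean. ATM-/- cells had 0 and 0 at 4 h, 2 and 0 at 8 h, 1 and 6 at 24 h, and 1 and 0 on the mean. Differences were 2 above at 4 h, 9 and 26 at 8 h, 6 and 4 at 24 h, and 5 and 16 on the mean, with an ATM+/+ let-7 median of 0.88.

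In leave-one-out settings, the ATM-/- count higher on the mean was 2 without 8 h and 7 without 24 h, and 6 were lower without 24 h. limma genotype calls were 25 and 42 with centred arrays, 25 and 32 with quantile normalization, 23 and 57 with the 75th percentile, and 33 and 1 above the median level, where 59 miRNAs were tested; 1 was lower without 8 h. With an intensity trend and robust prior limma made 3 calls higher in ATM+/+ cells and 1 for the difference of the responses.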

Other observations

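The tests below were chosen after the results were seen. The arrays pair by time, and 8 splits of the 8 arrays swap the genotypes within times. The real one, with 58 genotype calls on the deposited scale, was the 1 with as many, and the highest of the others gave 0. With 8 splits the smallest share is 0.125, too few for a share under 0.05. Another 24 splits, which leave some times undivided, gave at most 0 calls. Genotype, chip, normalization, and RNA recovery or labelling of the samples cannot be told apart.

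miRNAs of one genomic cluster differed between genotypes by unequal amounts. miR-143 was higher in ATM+/+ cells by 2.78 ± 0.24 (SD over 4 times) on the deposited scale and its neighbour miR-145 by 0.30 ± 0.20, a difference of 2.48 ± 0.18 within the arrays. miR-145 turned to lower values under the other 3 scalings, from -0.74 to -0.96. The pairs miR-199a-3p/miR-199b and miR-214 (4.76 ± 0.90 and 0.98 ± 0.46), miR-23b and miR-24 (4.23 ± 0.69 and 0.60 ± 0.31) and miR-222 and miR-221 (2.44 ± 0.21 and 1.02 ± 0.45) behaved alike. miR-24 has a second locus and the probe for miR-199a-3p/miR-199b also measures a product of another locus, so these 2 pairs are not comparisons within one transcript. An initial look at 5 clusters picked for this contrast was replaced by all 12 clusters with at least 2 members measured.

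One factor for a whole array cancels in a difference within arrays, so tests of it on these clusters were dropped. In 6 of the 12 the outermost members lay over 2 SD apart, and a first criterion of over 50% was not met. Simulations with no difference gave a mean of 0.53 such clusters and at most 4. Members of a cluster were no closer to each other than shuffled members: the mean absolute difference within clusters was 1.29, against a median of 1.30, at percentile 49.4. The count of 6 argues against an equal change of all members as the whole cause in those clusters. Among them are the 2 pairs above that are not comparisons within one transcript. A shared change in transcription as part of the cause is not shown and not excluded. Differences in maturation, or in hybridization or labelling that depend on sequence, may underlie the pattern, and could not be separated without probe sequences.

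A further hypothesis, that guide and passenger strands respond in opposite ways, stays open. In the authors' deposited table the guide strand lay above the passenger strand of the same precursor in 14 of 17 pairs in ATM+/+ cells, for example let-7b at 0.96 and let-7b* at -0.77. miR-30c enters with both miR-30c-1* and miR-30c-2*, so the pairs are not all separate. The strands taken as guides for miR-30c, miR-92a and miR-140 had lower 0 h intensities than their passengers. A first criterion, a share of at least 80%, was met, but it had no comparison with other miRNAs. Random partners at the intensity of the passenger strand gave the same median share of 82.4%, and the observed share lay at percentile 39.55. The guide lay above 0 and the passenger below 0 in 9 of the 17 pairs, at percentile 61.3 of random partners, so opposite responses of the 2 arms are neither shown nor excluded.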
